A study of Mus musculus with 16 samples.

How the data were processed

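RNA was sequenced from the cortex of AAV-injected mice in 16 libraries, 4 for each of 4 constructs. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was isolated from 1 μg of it with oligo(dT) beads, and the fragmented RNA was primed with random primers and amplified by PCR. No step that marks the strand is named, so reads of overlapping antisense genes cannot be told apart. The submitters' processing notes name FastQC 0.10.1 and cutadapt 1.9.1, and the genome builds GRCm39 and mm10; the aligner, the counter and the annotation were not given in the sources used here.

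The deposited table holds, per the file headers and its values, raw whole-number counts per gene and library beside FPKM values, fragments per kilobase of the gene's exonic length, scaled to the library total. The authors' FPKM values were recovered from the deposited counts, exonic lengths and library totals within 0.005, which is their rounding to 2 decimals. The table lists 55359 mouse genes and 4 construct sequences. Gene symbols, identifiers and coordinates were taken from the table, which does not name its build. Of 52083 identifiers shared with a GRCm38 (mm10) annotation, 2.88% had the same start, so printed coordinates are those of the table and not of mm10. The construct rows took at most 0.00714% of a library's counts and were left out of the tests. Groups were taken from the construct code in each library's title and the key in the series' design text. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples. No sequencing batch or date was given.

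Library totals were 12838756 to 19131210 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17737. The counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided), all 16 libraries in 1 fit and the group as the only term; the common biological coefficient of variation was 0.112. Genes were called at a Benjamini-Hochberg adjusted p threshold of 0.05 within each of the 6 comparisons between groups. A test on log2 FPKM with limma had been fixed for the case that the table held no counts, with this count test in its place if it did; the test on log2 FPKM was kept as an alternative. Log2 fold changes are printed with their standard errors, and group values as mean FPKM ± SD. Where all libraries of a group had 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio was given with its exact 95% interval. Such intervals and bounds cover counting error only, since reads were amplified by PCR without molecular identifiers. The analysis was tested on simulated counts for ATG-GGC100 against ATG-GGC11 over 17459 genes: 60%, 80%, 94% and 98% of genes changed by 1.5, 2, 3 and 4 times were recovered, and 7 of 173 calls were false.

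Before the data were examined, 50 gene lists (pathways, complexes, brain cell types, neighbouring regions and sex-linked genes) were fixed. They were tested with limma 3.58.1's camera on log2 CPM with a preset correlation of 0.01, adjusted over the lists within a comparison; the test was repeated with an estimated correlation, and with fry. Of the 126 calls of camera over 300 tests, 9 held with an estimated correlation, all in ATG-GGC100 against ATG-GGC11, and fry called 79. Members are counted as past the test over all genes and as adjusted over the list alone. A list of 32 hepatocyte genes was written after the data were examined. Named genes followed a rule also fixed before: in each direction the 10 largest changes past the test with a mean of at least 1 FPKM in the higher group and no overlap between the libraries of both groups; up to 4 called members of each list described; and a fixed set of glial and neuronal markers whether or not they passed. Members of near-identical families (C4a and C4b, Mup, Serpina1, Serpina3, H2, hemoglobin genes) can share reads and are uncertain one by one. Some genes that met the rule are not reported here.

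Alternatives fixed beforehand were a pseudocount of 1 or 0.1 on log2 FPKM with limma, other filters on low values (none, at least 1 FPKM and at least 5 FPKM in 4 libraries), median-ratio and quantile scaling, plainer and robust variance models, library weights, a fit of only the 8 libraries compared, the replicate number as a block, a threshold of 1.5-fold besides the adjusted p, DESeq2 1.42.0, and leaving out each library in turn. A covariate for Xist was planned for libraries that differ in it and was not run, since its highest count was 9. The striatal marker score as a covariate, library totals as scaling, and a filter on the counts of the other groups were added after the data were examined. Libraries of 1 group differed by a chi-square per degree of freedom of 4.86 to 23 over the 24 pairs, which does not show whether they came from separate animals. Term enrichment used the pathway annotations in the deposited table with the tested and annotated genes as background, and a one-sided hypergeometric test.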

Results

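Gene expression was measured by bulk RNA sequencing in the cerebral cortex of mice injected with adeno-associated virus (AAV), a viral vector that carries a gene into cells. The series asked how polyG proteins, chains of glycine encoded by GGC repeats, alter the cortical transcriptome in a model of neuronal intranuclear inclusion disease (NIID), a neurodegenerative disease with protein inclusions in cell nuclei. Its title names microglia, the resident immune cells of the brain. The 16 libraries formed 4 groups of 4, named after the construct: ATG-GGC11 with a short repeat, ATG-GGC100 and TAG-GGC100 with a long repeat, and ATG-GGN100dCT, in which GGN stands for any of the glycine codons. ATG is the usual start codon and TAG a stop codon; the meaning of dCT was not given in the sources used here. Library totals ran from 12838756 to 19131210 counts, and 17737 genes were tested.

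The construct sequences were counted beside the mouse genes, and each construct's row was highest in its own group. The ATG-GGC11 row had 51.6 ± 14 CPM (counts scaled to the library total; SD, n = 4) in its own libraries and a mean of at most 1.78 CPM in another group. The TAG-GGC100 row had 12.6 ± 1.95 CPM in its own libraries against at most 0.962 CPM elsewhere. The ATG-GGN100dCT row had 22.4 ± 11 CPM against at most 0.0472 CPM. The ATG-GGC100 row was low even in its own libraries, at 1.75 ± 0.564 CPM, and reached at most 0.167 CPM elsewhere. This was about the level of the ATG-GGC11 row in the same libraries, which also held 0.548 CPM on the TAG-GGC100 row. How reads that match several construct rows were counted was not given. The row values may therefore not show the level of each construct.

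The first comparison, ATG-GGC100 against ATG-GGC11, was between the long and the short repeat, both with ATG. Own construct rows differed as well, at 1.75 ± 0.564 against 51.6 ± 14 CPM. The repeat length and the construct level, as far as the rows show it, were therefore not separated. Own rows also stood lower in TAG-GGC100 and ATG-GGN100dCT than in ATG-GGC11, at 12.6 ± 1.95 and 22.4 ± 11 CPM. Genes of activated microglia were among the single genes that rose most. Clec7a (ENSMUSG00000079293, chromosome 6, 129438554 to 129449742 on the minus strand in the deposited table), a receptor for fungal glucans that marks disease-associated microglia, rose from 0.075 ± 0.0733 to 3.12 ± 0.478 FPKM (SD, n = 4 in each group), a log2 fold change of 5.28 ± 0.47 (SE; edgeR adjusted p = 1.2e-05). Cst7, the protease inhibitor cystatin F, rose from 0.112 ± 0.067 to 4.26 ± 1.13 FPKM, by 5.15 ± 0.53 on the log2 scale (adjusted p = 2.05e-05). The integrin gene Itgax rose by 3.72 ± 0.45 (adjusted p = 6.44e-05). Of the 22 measured genes of the disease-associated microglia list, 17 rose and none fell, and 19 rose when adjusted over the list alone. The median log2 fold change was 0.85 (camera adjusted p = 1.33e-24, and adjusted p = 0.0142 with an estimated correlation). The receptor gene Trem2 and its adaptor Tyrobp rose less steeply, by 1.03 ± 0.16 and 0.89 ± 0.14. The lipid carrier gene Apoe rose from 656 ± 94.9 to 912 ± 68.2 FPKM, by 0.43 ± 0.09. General myeloid markers rose too, in 10 of 13 members (11 when adjusted over the list alone; median 0.99, adjusted p = 0.0263 with an estimated correlation). Among them were the protease gene Ctss, from 50.5 ± 3.3 to 117 ± 12.5 FPKM, and the oxidase subunit gene Cyba. Homeostatic microglial genes moved less: 6 of 15 rose, or 13 when adjusted over the list alone, with a median of 0.46 and an adjusted p = 0.0842 with an estimated correlation. Of these markers, P2ry12 (18.6 ± 1.52 in ATG-GGC100 against 16.3 ± 0.957 FPKM, adjusted p = 0.617) and Tmem119 (11 ± 1.57 against 8.93 ± 0.453 FPKM, adjusted p = 0.213) did not pass the test.

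**Figure D1:**
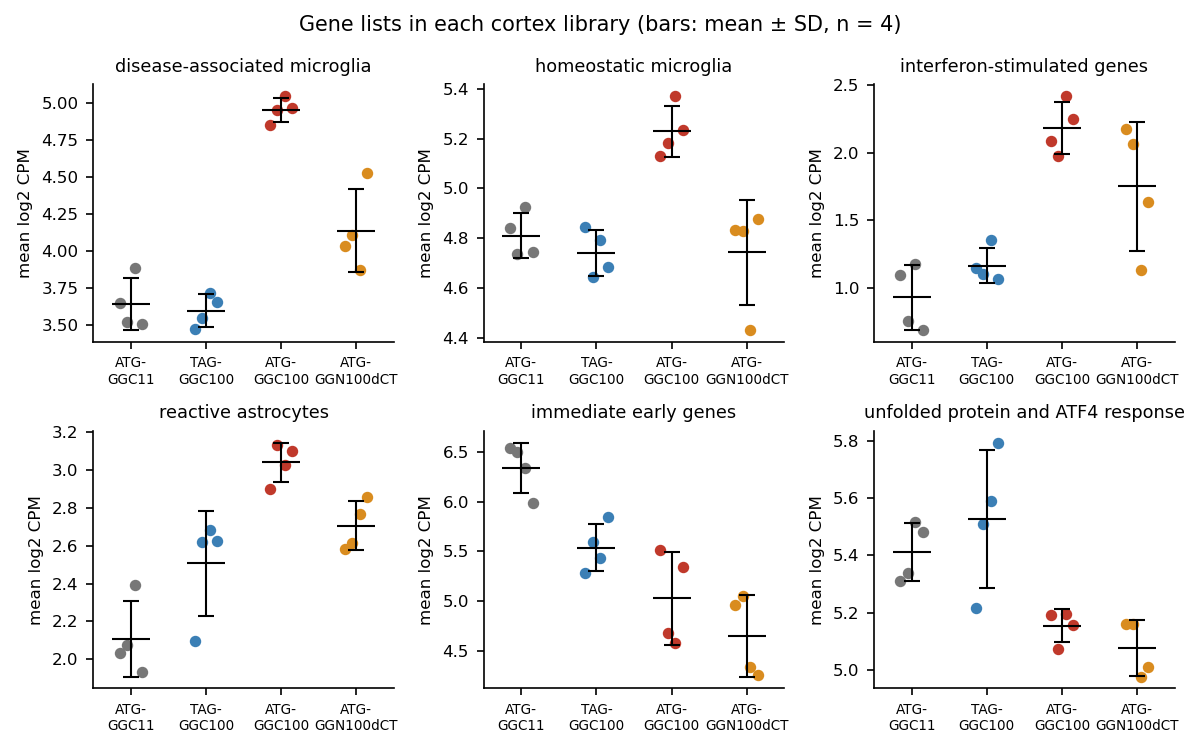
Mean log2 CPM of the members of 6 gene lists (y axis) in each library (points) of the 4 groups (x axis), with the group mean (line) and SD (bar), n = 4. The disease-associated microglia score was 4.96 ± 0.08 in ATG-GGC100, 3.64 ± 0.18 in ATG-GGC11, 3.6 ± 0.11 in TAG-GGC100 and 4.14 ± 0.28 in ATG-GGN100dCT. The immediate early gene score was highest in ATG-GGC11, at 6.34 ± 0.25.

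Interferon-stimulated genes, complement, antigen presentation and reactive astrocyte genes rose in the same comparison. Of 30 interferon-stimulated genes, 20 rose (29 when adjusted over the list alone), with a median log2 fold change of 1.25 (adjusted p = 0.0289 with an estimated correlation). The chemokine gene Cxcl10 rose from 0.0475 ± 0.0236 to 0.852 ± 0.246 FPKM, by 4.03 ± 0.58 on the log2 scale. Of 16 complement genes 10 rose (13 when adjusted over the list alone; adjusted p = 0.0142 with an estimated correlation). C4b rose from 4.23 ± 0.869 to 30.9 ± 7.21 FPKM (2.82 ± 0.31, adjusted p = 0.000261), C3 by 2.94 ± 0.45 and C1qa from 41.8 ± 7.02 to 102 ± 11.7 FPKM (1.24 ± 0.13). Reads of C4b can be shared with its near-identical neighbour C4a. Of 15 genes of MHC class I and antigen processing 8 rose (10 adjusted over the list alone; adjusted p = 0.0291 with an estimated correlation). H2-D1 rose by 1.13 ± 0.13 and the transactivator gene Nlrc5 by 2 ± 0.36. Reactive astrocyte genes rose in 9 of 24 members (11 adjusted over the list alone; adjusted p = 0.0142 with an estimated correlation). The filament gene Gfap went from 42.8 ± 9.47 to 193 ± 22.5 FPKM (2.13 ± 0.28, adjusted p = 0.00112) and the serpin gene Serpina3n from 5.26 ± 0.812 to 32.4 ± 9.2 FPKM. Of 25 autophagy and lysosome genes 8 rose (10 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation). The lysosomal protease gene Ctsd rose from 99.1 ± 8.39 to 166 ± 12.2 FPKM and the progranulin gene Grn by 0.54 ± 0.07. Border macrophage genes rose in 3 of 10 members, such as the mannose receptor gene Mrc1 by 1.36 ± 0.18 (5 adjusted over the list alone; adjusted p = 0.0289 with an estimated correlation). Meningeal fibroblast genes rose beside them, in 2 of 11 members (7 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), so a difference in attached meninges was not separated from a change in the border macrophages.

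Immediate early genes, which neurons switch on within minutes of activity, fell in ATG-GGC100 relative to ATG-GGC11. Of the 18 measured, 14 fell and none rose (15 fell when adjusted over the list alone), with a median log2 fold change of -1.29 (adjusted p = 0.0503 with an estimated correlation). Fos went from 33.4 ± 8.83 to 9.24 ± 4.22 FPKM (SD, n = 4; it fell by 1.9 ± 0.36 on the log2 scale, adjusted p = 0.0126) and Junb from 57.7 ± 12.9 to 21.3 ± 6.71 FPKM. Ccn1, a secreted matrix protein gene outside the list, fell by 2.18 ± 0.24 (adjusted p = 5.98e-05). Among 19 inhibitory neuron genes 5 fell and 2 rose (7 and 2 when adjusted over the list alone), with a median of -0.10 and an adjusted p = 0.237 with an estimated correlation. Lhx6, a transcription factor gene of interneurons, fell from 4.59 ± 0.331 to 2.95 ± 0.336 FPKM (log2 fold change -0.68 ± 0.09, adjusted p = 0.000122) and the receptor gene Erbb4 from 6.96 ± 0.465 to 5 ± 0.262 FPKM. Pvalb, the parvalbumin gene, stood at 31.8 ± 8.83 against 64.5 ± 8.64 FPKM (adjusted p = 0.026). Its call was lost without any 1 of ATG-GGC11 replicates 1, 3 and 4 or ATG-GGC100 replicates 2, 3 and 4, with an adjusted p of up to 0.0823. Of 20 voltage-gated channel genes 5 fell (6 adjusted over the list alone; adjusted p = 0.082 with an estimated correlation), among them Kcna2 and Kcnc1 by -0.48 ± 0.08 and -0.49 ± 0.08. Of 20 presynaptic genes 5 fell (6 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), with the vesicle protein gene Vamp1 from 17.3 ± 1.88 to 9.72 ± 0.902 FPKM. The pan-neuronal gene Rbfox3 (48 ± 1.28 against 50.7 ± 0.227 FPKM), the excitatory neuron gene Slc17a7 (231 ± 17 against 201 ± 15.2 FPKM) and the myelin gene Mbp (278 ± 25.1 against 320 ± 51.7 FPKM) did not pass the test.

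In all, edgeR's quasi-likelihood test called 621 genes at the adjusted p threshold of 0.05, 390 higher and 231 lower in ATG-GGC100. Of the calls 62.8% were higher, against 74.8% with library totals as scaling. The count was 345, 353 and 401 without ATG-GGC11 replicates 1, 2 and 4, and 370 and 307 without ATG-GGC100 replicates 2 and 3.

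**Figure D2:**
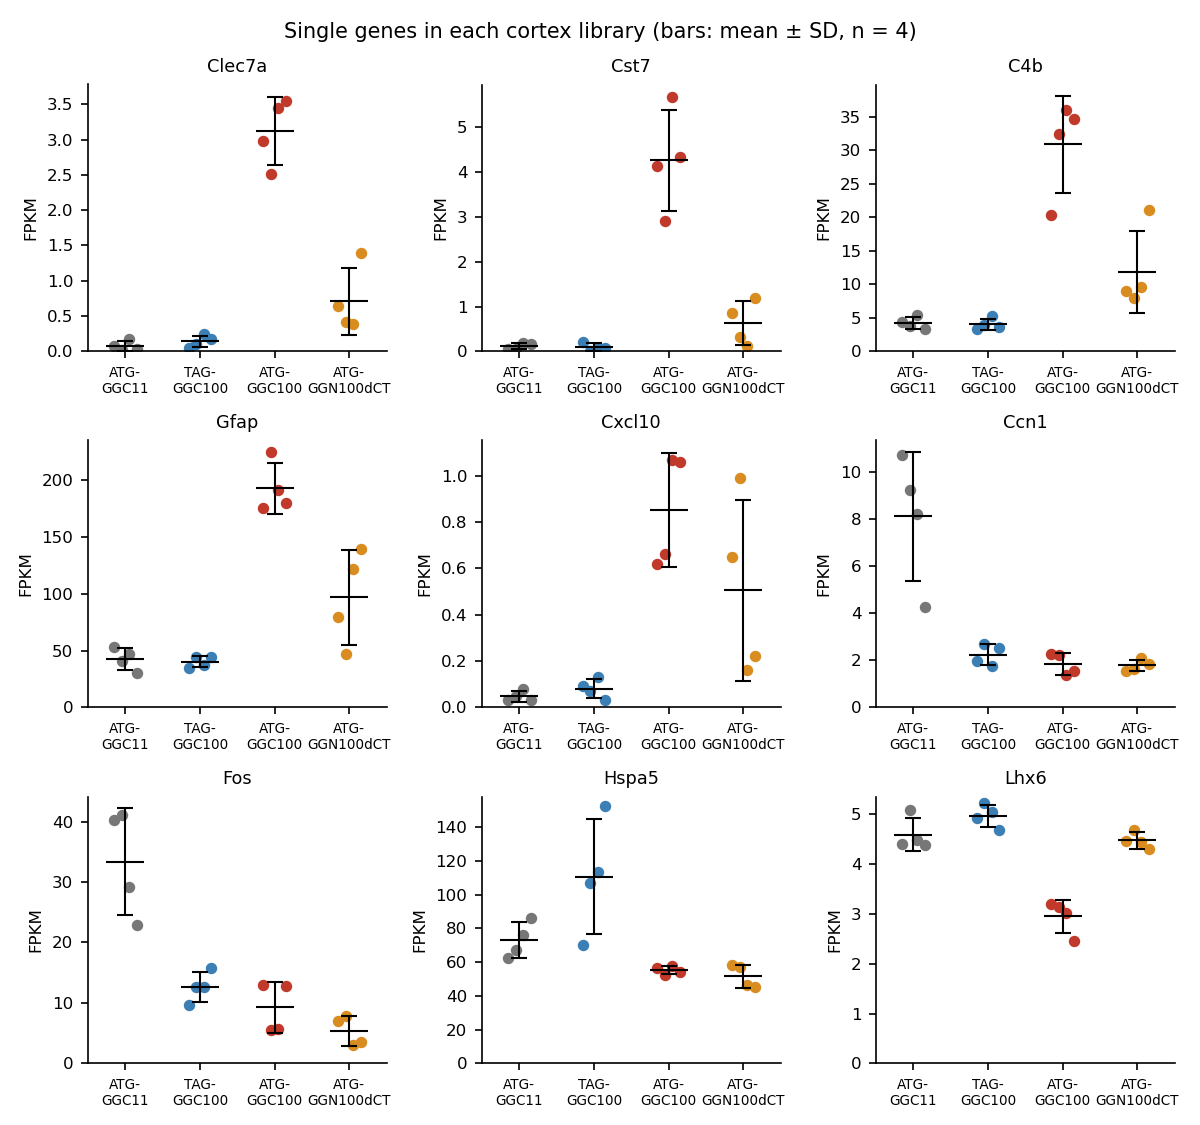
FPKM (y axis) of 9 genes in each library (points) of the 4 groups (x axis), with the group mean (line) and SD (bar), n = 4. Clec7a and Cst7 stood highest in ATG-GGC100, at 3.12 ± 0.478 and 4.26 ± 1.13 FPKM. Ccn1 and Fos stood highest in ATG-GGC11, and Hspa5 highest in TAG-GGC100, at 111 ± 33.9 FPKM.

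TAG-GGC100 against ATG-GGC11 put the long repeat with TAG beside the short repeat. Only Ccn1 (ENSMUSG00000028195, chromosome 3, 145352731 to 145355736 on the minus strand) passed the test, at 2.24 ± 0.442 against 8.11 ± 2.75 FPKM (SD, n = 4). It fell by 1.86 ± 0.24 on the log2 scale (edgeR adjusted p = 0.00502). Microglial and astrocyte genes that rose in ATG-GGC100 did not pass the test here. Clec7a stood at 0.14 ± 0.0829 FPKM (adjusted p = 0.912), Trem2 at 2.21 ± 0.187 FPKM, C1qa at 42.2 ± 3.61 FPKM, Cd68 at 5.02 ± 1.08 FPKM and Gfap at 40 ± 4.92 FPKM, all within the adjusted p range of 0.789 to 0.999. No member of the disease-associated list passed, over all genes or adjusted over the list alone. The median was -0.14 (adjusted p = 0.907 with an estimated correlation). Some lists moved when adjusted over the list alone, without a member past the test over all genes. Immediate early genes had 11 lower members of 18 and a median log2 fold change of -0.79 (camera adjusted p = 6.74e-14, and adjusted p = 0.384 with an estimated correlation). The unfolded protein and ATF4 response, which restores protein folding in the endoplasmic reticulum, had 13 higher and 1 lower of 26 (adjusted p = 0.839 with an estimated correlation). Heat shock and chaperone genes had 7 higher of 20 (adjusted p = 0.581 with an estimated correlation).

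At an unadjusted p under 0.05 this comparison held 1219 of the 17737 genes tested, where a share of about 0.05 falls without any effect. DESeq2 called 39. Without TAG-GGC100 replicate 1 the count was 25, of which 22 were higher. It was 3 without ATG-GGC11 replicate 4 or ATG-GGN100dCT replicate 3, and 2 without ATG-GGC100 replicate 2 or 3.

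ATG-GGN100dCT against ATG-GGC11 set the construct with other glycine codons and dCT in its name beside the short repeat. Immediate early genes fell in 16 of 18 members, the same number when adjusted over the list alone, with a median log2 fold change of -1.67 (adjusted p = 0.269 with an estimated correlation). Fos went from 33.4 ± 8.83 to 5.39 ± 2.45 FPKM (SD, n = 4; it fell by 2.67 ± 0.38, edgeR adjusted p = 0.0024), Fosl2 from 9.27 ± 0.526 to 2.14 ± 0.78 FPKM and Egr4 from 31.5 ± 4.45 to 9.31 ± 2.93 FPKM. Ccn1 fell by 2.24 ± 0.24. Interferon-stimulated genes rose in 12 of 30 members (22 adjusted over the list alone; median 0.89, adjusted p = 0.311 with an estimated correlation), with Cxcl10 at 0.505 ± 0.39 FPKM. Of the disease-associated microglia list 4 of 22 rose (8 adjusted over the list alone; median 0.27, adjusted p = 0.509 with an estimated correlation). Gpnmb, a glycoprotein gene of lipid-laden phagocytes, rose from 0.412 ± 0.107 to 1.22 ± 0.352 FPKM and Clec7a from 0.075 ± 0.0733 to 0.71 ± 0.474 FPKM. In contrast, Trem2 (2.46 ± 0.678 FPKM), Tyrobp (18 ± 4.39 FPKM) and C1qa (52.5 ± 10.6 FPKM) did not pass, and no homeostatic microglial gene passed.

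Reactive astrocyte genes rose in 7 of 24 members (9 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), with Serpina3n at 18.2 ± 6.99 FPKM (1.75 ± 0.29, edgeR adjusted p = 0.00502). Gfap, at 96.9 ± 42.1 FPKM, passed with an adjusted p = 0.0325, but not without any 1 of ATG-GGC11 replicates 2, 3 and 4 or ATG-GGN100dCT replicates 3 and 4, where its adjusted p reached up to 0.114. Markers of resting astrocytes went the other way, with 7 of 15 lower (8 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). Among them were the gap junction gene Gja1 (17 ± 0.903 in ATG-GGN100dCT against 21 ± 1.26 FPKM) and the receptor gene S1pr1 (40 ± 4.41 against 57.8 ± 4.89 FPKM). Of 19 inhibitory neuron genes 5 fell (6 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation), including the neuropeptide gene Cort from 9.04 ± 0.969 to 2.95 ± 0.867 FPKM. Of 15 pan-neuronal genes 3 fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), including the neurofilament gene Nefl from 114 ± 1.6 to 72.7 ± 14.2 FPKM. Complement genes rose in 6 of 16 members (8 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), with C3 from 0.0875 ± 0.0538 to 0.555 ± 0.17 FPKM.

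The ATG-GGN100dCT libraries also held transcripts of hepatocytes, the main cells of the liver, which make many complement proteins as well. Alb, the albumin gene (ENSMUSG00000029368, chromosome 5, 90608756 to 90624461 on the plus strand), stood at 9.93 ± 0.669 FPKM against 0.025 ± 0.0332 FPKM (8.36 ± 0.32 on the log2 scale, edgeR adjusted p = 1.12e-12). Serpina3k had 317 counts over the 4 libraries against 0, at least 110-fold higher with the floor of 3 counts set over the group. Mup3 had 270 counts against 1, a ratio of 280 with a 95% counting interval of 49.9 to 11100. Of 32 hepatocyte genes listed after the data were examined, 28 were tested and 26 passed. From this list 17 genes were picked that had at least 40 counts over the ATG-GGN100dCT libraries and few over the other 12. They summed to 56.7 to 63 CPM in each ATG-GGN100dCT library against a median of 0.37 CPM in the other 12. That contrast was fixed by the way they were picked. The whole list took 79.8 to 91.4 CPM in the ATG-GGN100dCT libraries and 4.27 to 14.7 CPM in the others. Reads can be shared within the Mup, Serpina1 and Serpina3 families. Red blood cell genes moved the other way, 2 of 5 lower (5 adjusted over the list alone; adjusted p = 0.315 with an estimated correlation).

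**Figure D3:**
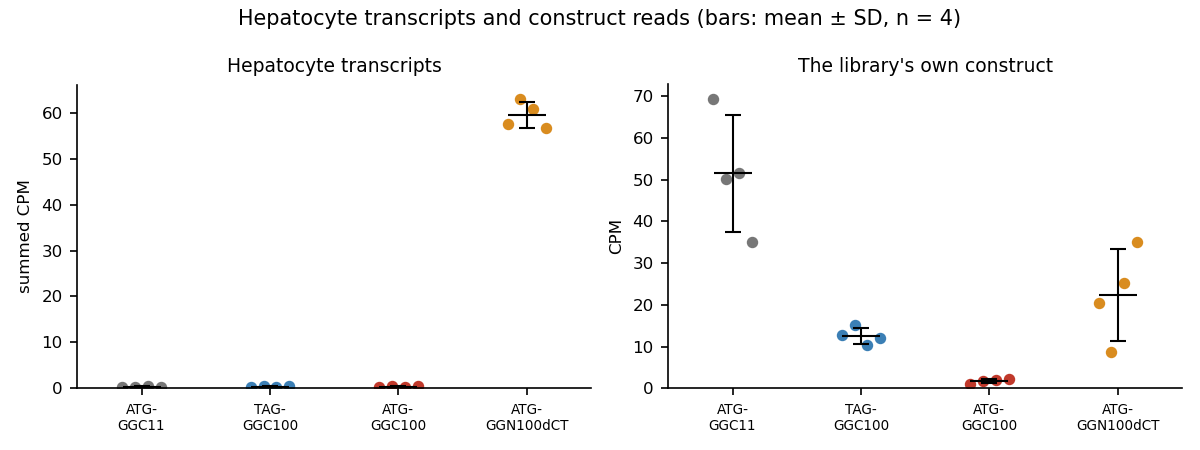
Left: summed CPM (y axis) of 17 hepatocyte genes picked as high in ATG-GGN100dCT and low elsewhere. Right: CPM (y axis) of each library's own construct row. Points are the libraries of the 4 groups (x axis), with the group mean (line) and SD (bar), n = 4. The 4 ATG-GGN100dCT libraries lay between 56.7 and 63 CPM for the hepatocyte genes, and between 8.65 and 35 CPM for their construct.

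The test called 1181 genes for ATG-GGN100dCT against ATG-GGC11, 562 higher and 619 lower. Of these 47.6% were higher, against 67.1% with library totals as scaling. The count was 702, 575, 634 and 723 without ATG-GGC11 replicates 1, 2, 3 and 4, and 1834, 553 and 386 without ATG-GGN100dCT replicates 2, 3 and 4. With only genes that had 20 counts or more outside ATG-GGN100dCT, it was 1117, with 520 higher and 597 lower.

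ATG-GGC100 against TAG-GGC100 held the repeat length and exchanged ATG for TAG. It is the direct test of the difference between the first comparisons. Reads of each group's own construct differed as well, on rows of 1340 bases, at 1.75 ± 0.564 against 12.6 ± 1.95 CPM. The start and the construct level, as far as the rows show it, were therefore not separated. The microglial genes were higher in ATG-GGC100. Cst7 stood at 4.26 ± 1.13 against 0.0875 ± 0.0881 FPKM (SD, n = 4; log2 fold change 5.55 ± 0.56, edgeR adjusted p = 1.62e-05), Clec7a at 3.12 ± 0.478 against 0.14 ± 0.0829 FPKM (4.42 ± 0.43) and Itgax at 0.765 ± 0.232 against 0.0175 ± 0.00957 FPKM (5.12 ± 0.53). Of 22 disease-associated genes 18 were higher (21 higher and 1 lower adjusted over the list alone; median 0.94, adjusted p = 0.0624 with an estimated correlation). So were 11 of 13 myeloid markers (12 adjusted over the list alone; adjusted p = 0.0743 with an estimated correlation) and 9 of 15 homeostatic genes (12 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). Interferon-stimulated genes were higher in 17 of 30 members (26 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). MHC class I genes were higher in 11 of 15 (12 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation) and complement genes in 10 of 16 (12 adjusted over the list alone; adjusted p = 0.0743 with an estimated correlation). Bst2, which encodes an antiviral membrane protein, stood at 7.13 ± 1.35 against 2.34 ± 0.398 FPKM and Gfap at 193 ± 22.5 against 40 ± 4.92 FPKM. C4b was higher by 2.89 ± 0.31 on the log2 scale.

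Genes of the unfolded protein and ATF4 response were lower in ATG-GGC100, 13 of 26 with 1 higher (16 lower and 2 higher adjusted over the list alone, median -0.40, adjusted p = 0.182 with an estimated correlation). The list score was 5.15 ± 0.06 in ATG-GGC100, 5.08 ± 0.1 in ATG-GGN100dCT and 5.53 ± 0.24 in TAG-GGC100. ATG-GGC11, which also carries ATG, stood at 5.41 ± 0.1, so the lower values did not go with ATG alone. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 55.2 ± 2.44 FPKM in ATG-GGC100 against 111 ± 33.9 FPKM in TAG-GGC100 (SD, n = 4; log2 fold change -1.04 ± 0.18, edgeR adjusted p = 0.00396) and Creld2 at 8.78 ± 1.08 against 17.9 ± 5.32 FPKM. Heat shock and chaperone genes were lower in 5 of 20 members (11 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). Voltage-gated channel genes were lower in 8 of 20 members (9 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), among them Kcnc1 at 15.2 ± 1.35 against 20.7 ± 1.89 FPKM. Lhx6 was lower by a log2 fold change of -0.79 ± 0.09. In contrast to the comparison with the short repeat, immediate early genes had 1 higher and 1 lower member of 18 past the test (1 and 1 adjusted over the list alone; median -0.46, adjusted p = 0.407 with an estimated correlation).

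This comparison called 1320 genes, 719 higher and 601 lower in ATG-GGC100. Of these 54.5% were higher, against 70.1% with library totals as scaling. The count was 620 and 689 without ATG-GGC100 replicates 2 and 3, and 526 without TAG-GGC100 replicate 2.

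ATG-GGN100dCT and TAG-GGC100 differed in the start, the repeat sequence, what dCT stands for and the length of the construct row (1063 against 1340 bases). This comparison cannot separate these. Protein-folding genes were the most widely lower: 14 of 26 unfolded protein response genes (17 adjusted over the list alone; median -0.43) and 13 of 20 heat shock and chaperone genes (15 adjusted over the list alone; median -0.34) were lower and none higher, each with an adjusted p = 0.597 with an estimated correlation. Hspa5 stood at 51.7 ± 6.86 against 111 ± 33.9 FPKM (SD, n = 4; log2 fold change -1.14 ± 0.18, edgeR adjusted p = 0.00409), Pdia4, a disulfide isomerase gene, at 13.7 ± 2.13 against 28.4 ± 7.24 FPKM. Sdf2l1 stood at 5.43 ± 1.32 against 17.6 ± 8.4 FPKM. Immediate early genes were lower in 4 of 18 members (11 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), including Fosl2 at 2.14 ± 0.78 against 5.22 ± 0.848 FPKM. Pan-neuronal genes were lower in 4 of 15 members (6 lower and 2 higher adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), with Nefm at 32.6 ± 9.23 against 62.5 ± 9.83 FPKM. Inhibitory neuron genes were lower in 5 of 19 (6 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation), with Cort at 2.95 ± 0.867 against 8.36 ± 1.99 FPKM. Disease-associated microglial genes were higher in 6 of 22 members (9 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), with Gpnmb at 1.22 ± 0.352 against 0.362 ± 0.0759 FPKM and Cd68 at 9.26 ± 1.95 against 5.02 ± 1.08 FPKM. Interferon-stimulated genes were higher in 7 of 30 (14 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation), with Irf7 at 1.22 ± 0.243 against 0.425 ± 0.147 FPKM. Alb had 1462 counts against 1, a ratio of 1460 with a 95% counting interval of 262 to 57800.

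This comparison called 1542 genes, 762 higher and 780 lower in ATG-GGN100dCT. Of these 49.4% were higher, against 65.7% with library totals as scaling. The count was 650 and 600 without TAG-GGC100 replicates 2 and 4, and 772 and 515 without ATG-GGN100dCT replicates 3 and 4.

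ATG-GGN100dCT against ATG-GGC100 compared the constructs with ATG and the long repeat, and tested directly how far their effects differed. These constructs also differed in the repeat sequence, in what dCT stands for and in row length (1063 against 1340 bases). Their own rows had 22.4 ± 11 against 1.75 ± 0.564 CPM. The comparison cannot separate these differences. Microglial genes were lower in ATG-GGN100dCT: 12 of 22 disease-associated genes (17 lower and 1 higher adjusted over the list alone; median -0.60), 9 of 13 myeloid markers (12 adjusted over the list alone) and 9 of 15 homeostatic genes (12 adjusted over the list alone), each with an adjusted p = 0.106 with an estimated correlation. Cst7 stood at 0.628 ± 0.493 against 4.26 ± 1.13 FPKM (SD, n = 4; log2 fold change -2.77 ± 0.41, edgeR adjusted p = 0.000644), and Clec7a at 0.71 ± 0.474 against 3.12 ± 0.478 FPKM. Trem2 stood at 2.46 ± 0.678 against 5.03 ± 0.654 FPKM (-1.03 ± 0.16, adjusted p = 0.00185), Tyrobp at 18 ± 4.39 against 35.5 ± 1.98 FPKM and C1qa at 52.5 ± 10.6 against 102 ± 11.7 FPKM. Of 25 autophagy and lysosome genes 9 were lower (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), with Ctsd at 114 ± 16.7 against 166 ± 12.2 FPKM. Of 15 MHC class I genes 6 were lower (9 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), with B2m at 112 ± 17.9 against 186 ± 15.4 FPKM. Border macrophage genes were lower in 3 of 10 members (4 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), such as Mrc1 at 0.628 ± 0.0624 against 1.52 ± 0.118 FPKM. Meningeal fibroblast genes were lower beside them, in 2 of 11 members (7 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with Ogn at 3.16 ± 0.843 against 9.83 ± 1.24 FPKM (log2 fold change -1.64 ± 0.27, adjusted p = 0.00504), so attached meninges were not separated from the macrophages here either. Interferon-stimulated genes were lower in 2 of 30 members (5 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation). Gfap, C3 and Serpina3n did not pass the test, at adjusted p = 0.0853, 0.758 and 0.126. Lhx6 was higher, at 4.47 ± 0.161 against 2.95 ± 0.336 FPKM (0.60 ± 0.09), and the stress peptide gene Crh lower, at 3.91 ± 0.96 against 9.22 ± 1.73 FPKM. Pvalb, at 36.3 ± 10.3 against 31.8 ± 8.83 FPKM, and the immediate early genes, with 0 of 18 past the test over all genes or adjusted over the list alone (median -0.40, adjusted p = 0.696 with an estimated correlation), showed no difference beyond the spread between replicates in this test.

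This comparison called 363 genes, 152 higher and 211 lower in ATG-GGN100dCT. The count was 204 and 165 without ATG-GGC100 replicates 1 and 3, and 208, 688 and 205 without ATG-GGN100dCT replicates 1, 2 and 3. DESeq2 called 671.

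**Figure D4:**
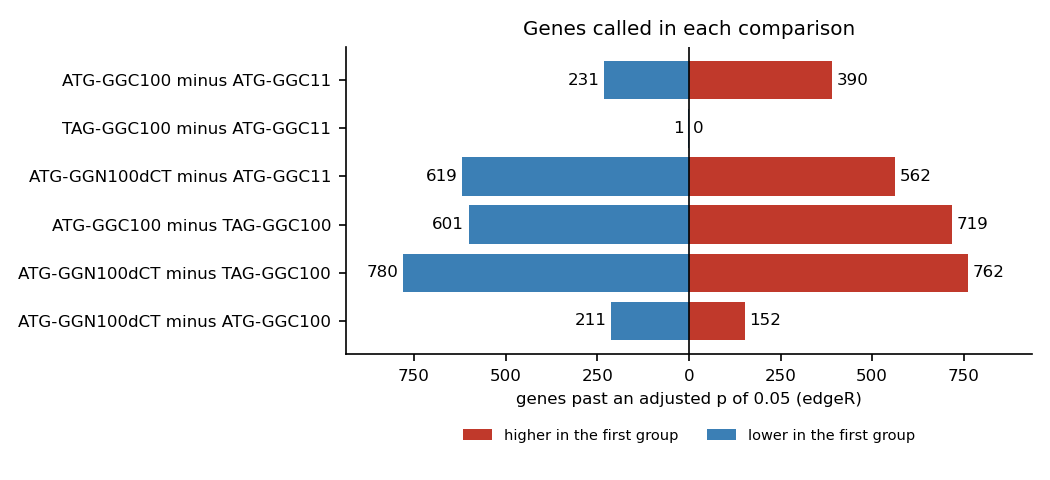
Number of genes called by edgeR (adjusted p threshold of 0.05) in each of the 6 comparisons, higher (bars to the right) and lower (bars to the left) in the group named first. The counts were lowest for TAG-GGC100 against ATG-GGC11, with 1 lower, and highest for ATG-GGN100dCT against TAG-GGC100, with 762 higher and 780 lower.

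The comparisons with ATG-GGC11 share its 4 libraries, so their fold changes correlate even without an effect. The 17737 genes are not independent replicates. Across them, the log2 fold changes of ATG-GGC100 and ATG-GGN100dCT had a Pearson correlation of 0.53 and a Spearman correlation of 0.56. Simulations of unchanged groups gave 0.50 and 0.46. In these, all libraries, the shared short-repeat ones too, were drawn gene by gene from the ATG-GGC11 means. The covariance was 0.0856 against 0.0286 simulated, a difference of 0.057. With the short-repeat libraries split between the comparisons the Pearson correlation averaged 0.33. Called in both were 117 genes higher and 120 lower, where independent lists would share 12.4 and 8.06, a reference that leaves out the shared libraries. With the short-repeat libraries split, a mean of 9.5 higher and 17.8 lower genes were called in both, where independent lists would share 0.9 and 0.4. Both parts of a split are still ATG-GGC11 libraries. A shift of that whole group would therefore also give shared calls and cannot be told apart from a common effect. For ATG-GGC100 and TAG-GGC100 the Pearson correlation was 0.26 against 0.50 simulated, and the covariance 0.0239 against 0.0286 simulated. With split libraries the correlation averaged 0.00. For TAG-GGC100 and ATG-GGN100dCT the correlation was 0.27 against 0.50 simulated, and the covariance 0.0312 against 0.0287 simulated. The correlation with split libraries averaged 0.06.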

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

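The tests of the hepatocyte transcripts were chosen only after those transcripts had been seen. The 17 hepatocyte genes used were picked as high in the ATG-GGN100dCT libraries and low in the other 12, so that contrast is not a test. Their sum lay between 56.7 and 63 CPM in all 4 ATG-GGN100dCT libraries. Their gene-by-gene makeup did not differ between these libraries beyond counting error (chi-square p = 0.791), as 1 shared source of liver RNA or of liver reads would give. The summed CPM varied by a ratio of 1.11 (95% interval 1.01 to 1.22) while the construct's own CPM varied by 4.05, which argues against expression in proportion to the construct. The genes took at most 0.0063% of a library's counts, and the whole hepatocyte list at most 0.00914%. These shares are too small to move other genes through scaling, but liver transcripts outside the list were not counted. Hepatocyte genes do add to the calls themselves in ATG-GGN100dCT against ATG-GGC11. There 16 of the 17 passed, and 26 of the 28 tested genes of the whole list. A candidate explanation is therefore RNA or reads from liver shared by the 4 libraries, for which the labels give no batch to test, and an effect of the construct that does not follow its level stays open.

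The construct rows, outside the gene comparisons, held reads above the other groups in each case: 51.6 CPM for ATG-GGC11 (at most 1.78 elsewhere), 1.75 CPM for ATG-GGC100 (at most 0.167), 12.6 CPM for TAG-GGC100 (at most 0.962) and 22.4 CPM for ATG-GGN100dCT (at most 0.0472).

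Among 532 tests for 1 library far from the other 3 of its group, 38 stood out, where chance gives about 26.6, or about 1 in 20 groups. The library far from its group in mitochondrial share was ATG-GGC100 replicate 4, at 7.245%. In mean log2 CPM of a list it was ATG-GGN100dCT replicate 3 for homeostatic microglia (4.43) and replicate 4 for complement (3.41), ATG-GGC11 replicate 3 for myeloid markers (3.53), and TAG-GGC100 replicate 1 for reactive astrocytes (2.09), replicate 4 for astrocyte markers (7.16) and replicate 3 for the striatum (6.32, the others at most 4.89). In ATG-GGC11, replicate 3 stood apart in FPKM of Grn (14.8), Hba-a2 (8.56), C1ra (0.76), S1pr1 (65.13), Lcn2 (0.78), Fcrls (12.98) and H2-K1 (10.35), replicate 4 in Arc (120.24) and Atf3 (1.41), replicate 2 in Lhx6 (5.08) and replicate 1 in Kcna2 (28.77). In ATG-GGC100, replicate 1 stood apart in FPKM of Itgax (0.42), Serpina3n (18.67), Mbp (315.78), Rims1 (28.01) and Hbb-bt (6.39), replicate 4 in Lgals3 (1.74) and Cartpt (4.05), replicate 3 in Ifit3 (11.46) and Hexa (38.12) and replicate 2 in Slc17a7 (256.83). In TAG-GGC100, FPKM of Hba-a2 was apart in replicate 4 (6.03), of C1ra and Fcrls in replicate 2 (1.43 and 8.12) and of Bst2 in replicate 1 (1.75). In ATG-GGN100dCT, replicate 4 stood apart in FPKM of C4b (21.01), replicate 3 in Sst (236.97), Hbb-bt (0.34) and Bst2 (2.31), and replicate 2 in Slc1a3 (64.36) and Lcn2 (2.27).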

How the results depend on the processing

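The striatal covariate, library totals as scaling and the filter on counts of the other groups were chosen after the data were examined; the rest were planned. Named genes kept their direction and side of the threshold in 7552 results, lost a call in 490, gained 1 in 21 and changed direction in 16, each of the last a gene not called. Tests of the lists called kept theirs in 2680, lost a call in 342 and changed direction in 2. Of the named genes called, 43 of 54 were called under every alternative that tested them in ATG-GGC100 against ATG-GGC11, 27 of 46 in ATG-GGN100dCT against ATG-GGC11, 34 of 44 in ATG-GGC100 against TAG-GGC100, 22 of 36 in ATG-GGN100dCT against TAG-GGC100, 26 of 44 in ATG-GGN100dCT against ATG-GGC100, and Ccn1 in TAG-GGC100 against ATG-GGC11. The filter of 5 FPKM left some of these genes untested, Clec7a and Ccn1 among them. The 1.5-fold threshold was applied to the counts of genes called and not to named genes. Some of these changed by less, such as Apoe and Grn in ATG-GGC100 against ATG-GGC11. A covariate for Xist was not run, since no library had more than 9 counts of it. Where a value below moved, the cause was not tested.

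For ATG-GGC100 against ATG-GGC11 (621 genes), the count was 251 with a filter of at least 5 FPKM, 393 by limma with quantile normalization and a pseudocount of 1 (431 without that normalization) and 382 with a 1.5-fold threshold. For TAG-GGC100 against ATG-GGC11 (1 gene), it was 22 without a filter, 2 without robust estimation, 22 with the 8 libraries alone and 39 in DESeq2. With the filter of 5 FPKM it was 0 in edgeR, with 572 of 8272 genes at an unadjusted p under 0.05. For ATG-GGN100dCT against ATG-GGC11 (1181), it was 779 by limma with a pseudocount of 0.1, 776 with the filter of 5 FPKM, 698 by limma without trend, 703 with the 8 libraries alone and 488 with the fold threshold. For ATG-GGC100 against TAG-GGC100 (1320), it was 718 with the filter of 5 FPKM and 573 with the fold threshold. For ATG-GGN100dCT against TAG-GGC100 (1542), it was 1015 and 969 by limma with pseudocounts of 1 and 0.1, 871 with the filter of 5 FPKM, 1007 by limma with quantile normalization, 986 by limma without trend, 634 with the 8 libraries alone and 567 with the fold threshold. For ATG-GGN100dCT against ATG-GGC100 (363), it was 239 and 210 by limma with pseudocounts of 1 and 0.1, 556 without a filter, 195 with the filter of 5 FPKM, 230 by limma without trend, 181 with the 8 libraries alone, 671 in DESeq2, 548 with the striatal covariate and 181 with the fold threshold.

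Leaving out each library in turn gave 307 to 766 genes, 1 to 25, 386 to 1834, 526 to 1655, 515 to 2123 and 165 to 688 in the order above. The replicate block gave 530, 2, 892, 1007, 1135 and 265 genes. Libraries with the same number did not deviate together (correlations of -0.21 to 0.19, 3 of 24 over 0.1, and in 3 of 24 pairs of libraries with the same number the first correlated best with its own number), so the numbers were not taken to pair them.

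Trem2 in ATG-GGN100dCT against ATG-GGC11, at a log2 fold change of -0.01, turned to 0.01 by limma with either pseudocount, with the filter of 1 FPKM and without trend, to 0.13 with library weights and to 0.04 with library totals, and ran from -0.12 to 0.17 over left-out libraries. Tyrobp turned to 0.04 with library weights and ran from -0.21 to 0.05. In TAG-GGC100 against ATG-GGC11, C1qa ran from -0.06 to 0.13 and Gfap from -0.23 to 0.02 over left-out libraries. The NF-kB and inflammasome list there (adjusted p = 0.00174) turned downward by limma with pseudocounts of 1 and 0.1 (adjusted p = 0.971 and 0.922). Against 126 list calls, 9 were made with an estimated correlation and 79 by fry, and 116 to 147 over left-out libraries. Without ATG-GGN100dCT replicate 3 the lists called went from 19 to 29 for ATG-GGN100dCT against ATG-GGC11 and from 13 to 23 against TAG-GGC100, and without TAG-GGC100 replicate 1 from 18 to 11 for TAG-GGC100 against ATG-GGC11. The Pearson correlation of fold changes was 0.33 for ATG-GGC100 and TAG-GGC100 by limma with a pseudocount of 0.1, 0.00 with split controls and 0.20 to 0.39 over left-out libraries. For ATG-GGC100 and ATG-GGN100dCT it was 0.58 by limma with a pseudocount of 1, 0.33 with split controls and 0.46 to 0.58 over left-out libraries. For TAG-GGC100 and ATG-GGN100dCT it was 0.36 and 0.39 by limma, 0.06 with split controls and 0.18 to 0.36 over left-out libraries. In simulated counts of ATG-GGC100 against ATG-GGC11 at the depth of these libraries, 60% of genes changed by 1.5 times were recovered, 25% of those under 21.1 CPM and 92.3% of those above; sequencing depth itself was not varied.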

Other observations

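Tests of the handling of the ATG-GGC11 animals, of the share of neurons and of the gap between microglial lists were chosen only after the results were seen. Other gene groups moved in ATG-GGC100 against ATG-GGC11. Of 19 genes of cholesterol synthesis 3 fell (8 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), among them Cyp51, from 19.7 ± 1.86 to 14.6 ± 1.9 FPKM (SD, n = 4; edgeR adjusted p = 0.00918). Cytokine and chemokine genes rose in 6 of 13 members (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.0263 with an estimated correlation), with Ccl3, a chemokine of activated microglia, from 0.2 ± 0.188 to 2.45 ± 0.546 FPKM. MHC class II genes rose in 3 of 9 members (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.082 with an estimated correlation). In the pathway annotation of the deposited table, the genes higher in ATG-GGC100 held 26 of 133 Phagosome genes where 4.46 were expected (adjusted p = 1.53e-11) and 22 of 118 Lysosome genes where 3.96 were expected (adjusted p = 2.11e-09).

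Relative to TAG-GGC100, genes of Protein processing in endoplasmic reticulum stood out among the lower genes, with 20 of 164 in ATG-GGC100 (6.37 expected, adjusted p = 0.0016) and 31 of 164 in ATG-GGN100dCT (8.3 expected, adjusted p = 3.42e-08). Of the 3 monocyte and neutrophil genes measured, 2 were higher in ATG-GGN100dCT than in ATG-GGC100 (2 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation). S100a8 stood at 1.07 ± 0.184 against 0.0825 ± 0.0954 FPKM and S100a9 at 2.35 ± 0.618 against 0.322 ± 0.16 FPKM (SD, n = 4; edgeR adjusted p = 0.0342 and 0.0242). Both calls were lost by limma with a pseudocount of 0.1. The S100a9 call was also lost, at an adjusted p of up to 0.0964, without any 1 of ATG-GGC100 replicates 1, 2 and 3 or ATG-GGN100dCT replicate 3, and the S100a8 call, at up to 0.109, without any 1 of the ATG-GGC100 libraries or of ATG-GGN100dCT replicates 1, 3 and 4.

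Microglial and interferon genes were higher in ATG-GGC100. A lower share of neurons would raise every other cell type alike, but the highest median log2 fold change of 4 other cell type lists was 0.11 against 0.99 for the myeloid markers (SE over members 0.12). Of the 22 disease-associated genes, 17 passed the test with the striatal score of each library as a covariate and 18 with library totals as scaling, against 17 in the main test, which argues against the striatal content of the pieces or the scaling as the whole cause. Of 17 genes of T cells and NK cells 3 were tested and 1 rose (1 adjusted over the list alone; adjusted p = 0.0982 with an estimated correlation), with list scores of 1.88 ± 0.31 in ATG-GGC100 and 1.24 ± 0.15 in ATG-GGC11, so entry of lymphocytes was not excluded. A change in microglial number and a change in their state may both contribute, and the construct stays the design's own explanation.

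The gap between the disease-associated and the homeostatic list score was larger in ATG-GGC100 than in ATG-GGC11 by 0.89 (all 4 libraries beyond all 4; exact permutation p = 0.0286, the smallest possible with 4 against 4, and adjusted p = 0.0686 over 12 tests, so it did not pass the correction). The size of this difference against the spread of the gaps (-0.27 ± 0.04 and -1.17 ± 0.09) argues against an equal rise of all microglial genes, as a hypothesis formed on the same data.

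Immediate early genes were lower than in ATG-GGC11 in 14 of 18 members in ATG-GGC100 and 16 in ATG-GGN100dCT, and in TAG-GGC100 in none over all genes in edgeR but 11 adjusted over the list alone; with an estimated correlation no list call held (adjusted p = 0.0503, 0.269 and 0.384). The striatal score as a covariate left the median log2 fold change of the list in ATG-GGC100 at -1.28, against -1.29 without it, with 14 of 18 members still past the test, which argues against striatal content. The median was -0.79 in TAG-GGC100 and -1.67 in ATG-GGN100dCT, so a higher level in the ATG-GGC11 animals, for instance from handling before tissue collection, could be a source of it. All 3 comparisons rest on the same 4 ATG-GGC11 libraries. For these decreases, and for that of Ccn1 in each of the 3, such a higher level and an effect of the constructs therefore cannot be told apart. It does not bear on ATG-GGN100dCT against TAG-GGC100, where 4 of 18 members were lower (11 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), with list scores of 4.66 ± 0.41 and 5.54 ± 0.24.

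It was also tested whether inhibitory neuron genes changed apart from excitatory neuron genes in ATG-GGC100. The gap between both list scores differed from that in ATG-GGC11 by -0.06 (exact permutation p = 0.657, adjusted p = 0.788 over 12 tests), so the test did not detect a difference in these libraries.

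Each comparison was set against all 35 splits of its 8 libraries into 4 and 4. For ATG-GGC100 against ATG-GGC11 only the real split, 1 of 35, gave as many as 621 genes, and the highest other gave 0 in edgeR. The real split was also the only 1 of 35 to reach its count in ATG-GGN100dCT against ATG-GGC11 (1181 genes, highest other 14) and ATG-GGC100 against TAG-GGC100 (1320, highest other 280). The same held in ATG-GGN100dCT against TAG-GGC100 (1542, highest other 32) and ATG-GGN100dCT against ATG-GGC100 (363, highest other 116). A share of 1 of 35 is under 0.05 but is the smallest that these splits can give. The splits also treat the libraries as independent, which the labels do not state. The real split thus ranked first in these comparisons, without chance being excluded. For TAG-GGC100 against ATG-GGC11, 3 of 35 splits gave at least the 1 gene of the real split, with 2 as the highest other, so chance cannot be excluded.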
